A study of Mus musculus with 10 samples.

How the data were processed

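RNA from the laser-captured respiratory epithelium of the nose of 10 mouse embryos at E16.5 was measured on Affymetrix whole-transcript arrays, 1 array per embryo, 5 WT and 5 TKO. Per the labels' protocols, embryos were fixed in formalin and embedded in paraffin, the epithelium was cut from sections by laser capture, and RNA was extracted, amplified and labelled with kits made for fixed tissue. The deposited values are on the log2 scale. Per the submitters' processing notes and the labels, the authors made them with RMA in the Affymetrix Expression Console, which corrects the background, brings the arrays to a common distribution and summarises the probes of each probe set. The version of that program and the level of summary are not given in the sources used here, and the log2 scale was read from the values, which ran from 1.5 to 13.7. Scanner files were not used here, so other background corrections were not tried and no detection call is given.

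The table held 41345 probe sets. The platform's annotation gave exactly 1 gene symbol to 23521 of them, several to 1814 and none to 16010, which are unnamed here rather than without a gene. Of the named probe sets, 23328 matched a table of RefSeq genes (assembly GRCm38.p6) by Entrez ID, and no symbol needed updating. That table was used only for names and for which genes neighbour each other, since the array's own genome build is not given in the sources used here, and no coordinates are printed. For each of 22180 genes the probe set with the highest mean over all 10 arrays was kept, and genes whose mean lay below the 25th percentile, a log2 value of 4.58, were left out, which left 16635 genes. Of the changed genes, 59 had more than 1 probe set, and for 8 of them another probe set differed between genotypes in the other direction. The targeted microRNA genes, Cdc20b where its locus is described, and the sex-linked genes were fitted without this filter.

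Genotypes were compared with limma 3.58.1 in R 4.3.3: a linear model with labelled sex and genotype, moderated variances with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment, with a threshold of 0.05. Sex entered because it was unbalanced, with 4 females and 1 male among the WT and 2 females and 3 males among the TKO embryos. The 29 gene lists, fixed before the data were examined, covered multiciliation, cilia, the cell cycle, reported miR-34 and miR-449 targets, p53 and Notch genes, markers of the other cell types that a capture could hold, and RNA quality. Of 1189 listed genes 995 were tested, and 32 belonged to more than 1 list. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with limma's fry, and with an exact two-sided permutation test (252 assignments of the arrays, smallest p 0.00794) on a score per embryo, the mean over members of the values centred per gene. A list needed at least 5 tested members. The non-epithelial score is the mean of the scores of the mesenchyme, endothelium, skeletal muscle, cartilage, leukocyte and glia lists. Changed genes within 5 Mb of the targeted loci were counted against those elsewhere with Fisher's exact test, the targeted microRNA genes left out. That test treats neighbouring genes as independent.

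The genes named were the 12 with the largest increase and the 12 with the largest decrease among those past an adjusted p of 0.05 whose genotypes' arrays did not overlap. Gene models with systematic names (Gm numbers, Rik, LOC), predicted genes, and olfactory and vomeronasal receptors were left out of these 12. From each list up to 4 members were named, those past the threshold with the smallest p first and then those with the smallest p, and all the targeted microRNA genes and Cdc20b were named. Other genes named because a count was small or a feature was singled out are marked where they stand.

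The scripts were tested on arrays simulated from the real means and residual variances of the 16635 genes for TKO against WT, with 200 genes changed in each of 10 runs. Changes of 0.25, 0.5, 1 and 2 on the log2 scale were called for 5.0%, 51.0%, 92.4% and 98.8% of the changed genes, and 4.73% of the calls were false. A list shifted by 0.2 was called by camera in 20 of 20 runs, and 1 of 560 unshifted lists was called; genes were simulated as independent, which the members of a real list are not. Figures were drawn with matplotlib 3.10.9.

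The alternatives tried were a model without sex, the replicate number as a block, other filters on dim genes, 2 further scalings, other variance models, array weights, array quality as a covariate, the mean of a gene's probe sets, females only, each array left out in turn, all probe sets, other list settings, and wider windows around the loci. The non-epithelial score as a covariate and the fit without genes near the loci were added after the data were seen. A test of seed sites in 3' untranslated regions was planned and not run, since no transcript sequences were given.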

Results

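Gene expression was measured in the respiratory epithelium of the nose, the ciliated lining of the nasal passages, of mouse embryos at E16.5. The epithelium had been cut out of paraffin sections by laser capture, and its RNA was hybridised to Affymetrix whole-transcript arrays, 1 array per embryo. There were 5 wild-type (WT) embryos, of which 4 were labelled female and 1 male (WT 3), and 5 embryos lacking the miR-34 and miR-449 microRNA families (triple knockout, TKO), of which 2 were labelled female and 3 male (TKO 2, TKO 4 and TKO 5). These microRNAs share a seed sequence and are known for their high level in multiciliated cells. The single comparison of the design, TKO minus WT, asks which genes change in this epithelium when they are lost. Values are RMA values on the log2 scale, and across all probe sets the arrays correlated with one another at 0.975 to 0.989. The levels of Xist, the transcript that silences the X chromosome in females, and of the Y-linked gene Uty matched the labelled sex on every array: Xist was 10.9 ± 0.14 (SD, n = 6) in females and 4.94 ± 0.18 (SD, n = 4) in males. The number of arrays, 5 per genotype, limits the precision, and the labels do not say whether embryos shared a litter.

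The probe sets for the targeted genes were read first. Mir449c was 7.26 ± 0.28 in WT and 3.67 ± 0.49 in TKO (SD, n = 5 each), and Mir449a was 7.20 ± 0.31 in WT and 5.41 ± 0.29 in TKO. On single arrays, Mir449c lay between 6.80 and 7.56 in WT and between 3.16 and 4.39 in TKO, and Mir449a lay between 6.86 and 7.56 in WT and between 5.06 and 5.76 in TKO. With sex in the model, Mir449c fell by 3.41 (limma adjusted p = 2.6e-05) and Mir449a fell by 1.81 (limma adjusted p = 0.000442). Mir449b was bright in both genotypes, at 12.17 ± 0.04 in WT and 11.79 ± 0.17 in TKO, and fell by 0.33 (limma adjusted p = 0.0318). The Mir34b probe set was at 5.76 ± 0.15 in WT and 5.49 ± 0.07 in TKO, with a log2 change of -0.28 that missed the threshold in limma (adjusted p = 0.166) while its arrays did not overlap (exact permutation p = 0.00794, the smallest that 5 against 5 can give). Mir34a and Mir34c were near the bottom of the array's range in both genotypes: Mir34a was 3.46 ± 0.13 in WT and 3.40 ± 0.26 in TKO, and Mir34c was 3.28 ± 0.08 and 3.11 ± 0.09, with limma adjusted p of 0.633 and 0.318. Where the deletions lie relative to these probes is not given in the sources used here, and a probe set outside a deleted part checks nothing. Cdc20b, the gene whose intron holds the Mir449 cluster, rose from 9.99 ± 0.21 to 11.33 ± 0.13, and with sex in the model its increase was 2.66-fold (limma adjusted p = 4.37e-05). The folds given for genes come from the model with sex, while means and SDs are unadjusted, so that the Cdc20b means differ by 1.33 and its log2 change is 1.41.

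**Figure D1:**
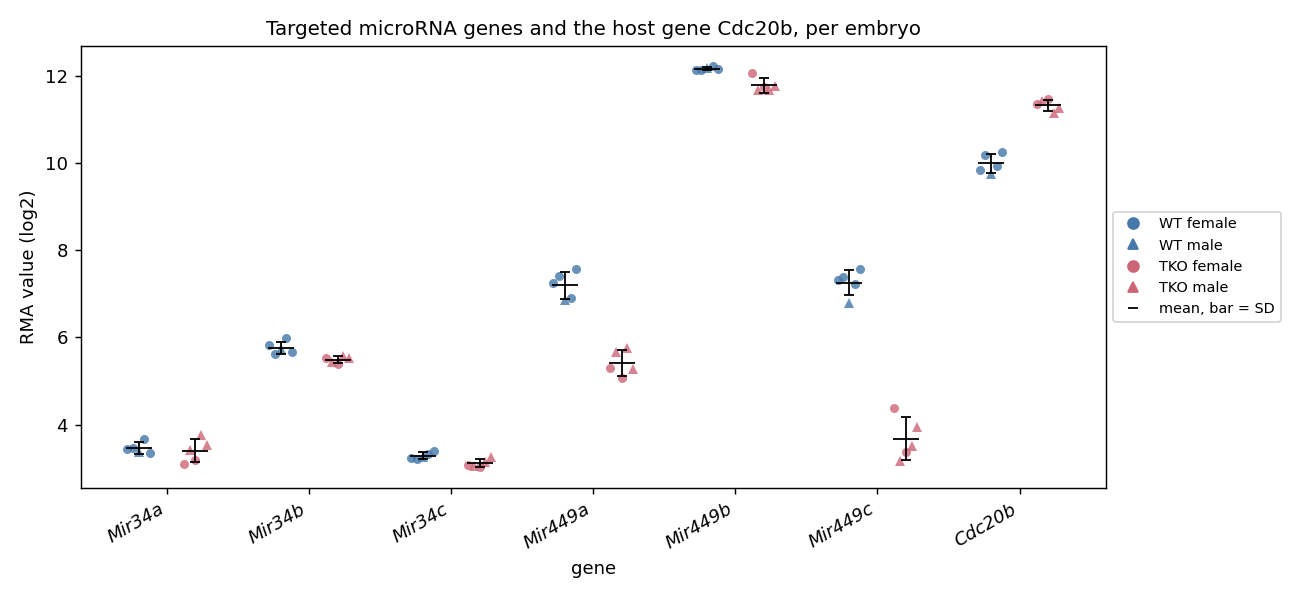
RMA values (log2) of the probe sets for the 6 targeted microRNA genes and for Cdc20b, with 1 point per embryo (circles female, triangles male), a horizontal line at the mean and bars of 1 SD, n = 5 per genotype. Mir449a and Mir449c are lower and Cdc20b is higher on every TKO array than on any WT array, while the Mir34a values of the genotypes overlap.

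More genes were higher than lower in the TKO epithelium. Among changed genes whose arrays did not overlap between genotypes, those that rose most were Ccdc192 (log2 change 1.77), Gzma, a granzyme of cytotoxic lymphocytes (1.65), the histone H4 gene H4c8 (1.56), Gmnc, the coiled-coil protein that starts the multiciliated cell programme (1.55), and Cdc20b (1.41). They were followed by Fam167a (1.36), Pnp2, a purine nucleoside phosphorylase (1.32), Ly6k (1.32), Tmem108 (1.31), Doc2b, a calcium sensor of vesicle release (1.25), Glipr1l1 (1.23) and the beta-defensin gene Defb25 (1.22). After Mir449c and Mir449a, the largest decreases among such genes were those of Ankub1 (-1.37), the neuronal transmembrane protein gene Slitrk6 (-1.37), Trim34a (-1.16), Ldlrad1 (-1.13), Shisal2a (-1.11) and the hydrolase gene Cmbl (-0.93). Btg4 (-0.88), the semaphorin receptor gene Plxnb3 (-0.81), Sytl1 (-0.80) and the craniofacial homeobox gene Alx1 (-0.75) completed the 12 largest decreases. Without WT 3 the change of Trim34a was -0.58 (limma adjusted p = 0.16). Others that then missed the threshold kept more of their change: H4c8 was at 1.65, Ly6k at 1.32, Ldlrad1 at -0.86, Shisal2a at -0.79, Cmbl at -0.79, Btg4 at -0.72, Plxnb3 at -0.66, Sytl1 at -0.84 and Alx1 at -0.59. The WT means of Pnp2 (3.92) and H4c8 (4.14) lay below the filter on dim genes at 4.58, so the size and rank of their changes are uncertain. A further probe set of Ly6k had a log2 change of -0.18.

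Of 16635 genes tested, 730 were higher and 186 lower in TKO at an adjusted p below 0.05 (limma with sex as a covariate and Benjamini-Hochberg adjustment). At that threshold 79.7% of the changed genes were higher, and the changes were mostly small: the median fold was 1.38 for the higher and 1.42 for the lower genes, and 28 genes were at least 2-fold higher and 17 at least 2-fold lower. The arrays of the genotypes did not overlap for 1265 genes, 7.60% of those tested, where chance gives 0.794%. The number of genes past the threshold depended on single arrays. It was highest without WT 5, at 1284, and the count lower in TKO ran from 19 without WT 3 to 398 without WT 5. Limma called 210 genes without WT 3, the only WT male, 307 without TKO 3 and 552 without TKO 1. The median change of the 916 genes, each in its own direction, was then 0.46, 0.45 and 0.49, against 0.48 with all arrays, and its median standard error rose from 0.096 to 0.12, 0.11 and 0.11. Of the 916 genes, 913, 916 and 916 had an unadjusted p below 0.05. The 916 genes were chosen on these same arrays, so keeping their size, direction and p in such fits was largely built in. A score of 6 non-epithelial marker lists was lower in TKO by 0.11 (exact permutation p = 0.405), and with it as a covariate 111 genes passed. The median change of the 916 genes went from 0.48 to 0.41 and its median standard error from 0.096 to 0.12, and all 916 kept their direction.

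**Figure D2:**
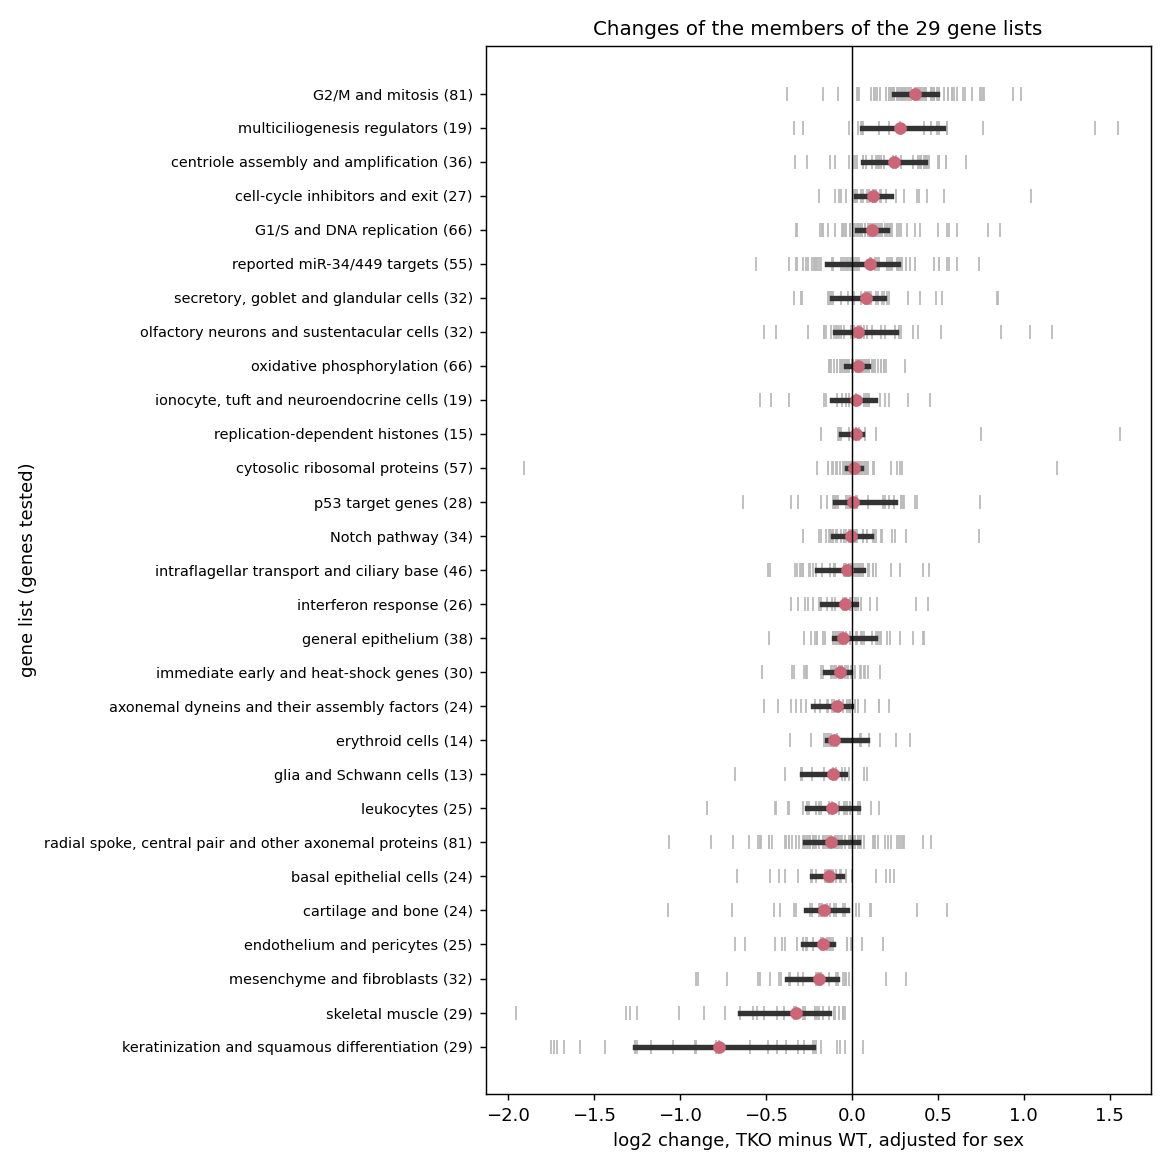
Log2 change (TKO minus WT, adjusted for sex) of the tested members of each of the 29 gene lists, with the number of tested genes in brackets; grey ticks are genes, the dark bar spans the middle quartiles and the red point is the median. The G2/M list has the highest median (0.37) and the keratinization list the lowest (-0.77).

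Of 19 tested regulators of multiciliation, 9 rose, none fell and 10 did not pass. Adjusted over the list alone, 11 rose and 2 fell. Gmnc rose from 7.52 ± 0.20 to 9.10 ± 0.15 (2.92-fold), Cdc20b rose 2.66-fold, Ccno, a cyclin-like protein needed for centriole amplification, rose from 9.44 ± 0.21 to 10.13 ± 0.09 (1.70-fold), and E2f5, a partner of the Gmnc and Mcidas proteins in transcription, rose from 7.03 ± 0.15 to 7.61 ± 0.07 (1.47-fold), each n = 5. The list's median change was 0.28, and camera placed it above the other genes (adjusted p = 1.58e-07, and adjusted p = 0.267 with an estimated correlation). The score per embryo was higher in all 5 TKO than in any WT embryo, by 0.34 (exact permutation p = 0.00794, adjusted over the 29 lists 0.0921). Without the genes within 5 Mb of the knocked-out loci, 6 of 15 members rose and the median was 0.21 (camera adjusted p = 0.000166). No score per embryo without those genes is given here. With the non-epithelial score as a covariate the list's median was 0.16.

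Centriole assembly and amplification is the step in which a cell makes the many basal bodies of its cilia. Of 36 tested genes of this list, 14 rose, none fell and 22 did not pass; adjusted over the list alone, 19 rose and 1 fell. Plk4, the kinase that starts centriole duplication, rose 1.58-fold (9.20 ± 0.29 to 9.80 ± 0.10), Stil rose 1.46-fold, Tube1, a tubulin of the centriole, rose 1.42-fold, and Deup1, a deuterosome scaffold found in multiciliated cells, rose 1.42-fold (10.75 ± 0.17 to 11.21 ± 0.08). The median change was 0.25 (camera adjusted p = 3.83e-08, and adjusted p = 0.528 with an estimated correlation), and the score per embryo was higher by 0.22 (exact permutation p = 0.0159, adjusted 0.0921). With the non-epithelial score as a covariate the median was 0.12.

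Few genes of the built cilium passed. None of 24 tested axonemal dynein and dynein assembly genes passed: the smallest adjusted p were those of Dnah1 (log2 change -0.43, limma adjusted p = 0.0717), Dnah11 (-0.35), Dnali1 (-0.27) and Dnaaf5 (-0.30). Of 81 radial spoke, central pair and other axonemal genes, 2 rose, 4 fell and 75 did not pass; adjusted over the list alone, 4 rose and 16 fell. Ttll6, a tubulin polyglutamylase, rose 1.33-fold and the kinase gene Stk33 rose 1.37-fold, while Cfap58 fell 1.45-fold and Tekt3, a tektin of the doublet microtubules, fell 1.77-fold. Of 46 intraflagellar transport and ciliary base genes, 1 fell, Ift43 (1.23-fold, limma adjusted p = 0.0394, a call lost in 13 of 24 settings), and Ift57, Ift88 and Ttc21b had log2 changes of -0.32, -0.33 and 0.41 that did not pass; the list's median was -0.028 (camera adjusted p = 0.144), and of 26 settings 6 gained a call and 3 changed its sign. The medians of the dynein and the radial spoke lists were -0.090 and -0.12 (camera adjusted p = 0.0295 and 0.000864, and adjusted p = 0.817 for both with an estimated correlation), and their scores per embryo did not separate the genotypes (exact permutation p = 0.405 and 0.389). Both medians turned positive without WT 3, to 0.0098 and 0.0066. With sex in the model that fit takes the genotype effect from the females alone, so females only gave the same medians and is no separate check. With the non-epithelial score as a covariate the dynein median was -0.19, the radial spoke median -0.23 and the intraflagellar transport median -0.15, and camera with the preset correlation called all 3 lists lower (adjusted p = 3.69e-05, 3.41e-09 and 4.8e-05). Without the covariate, an estimated correlation gave intraflagellar transport an adjusted p of 0.85, and the covariate was not combined with an estimated correlation.

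**Figure D3:**
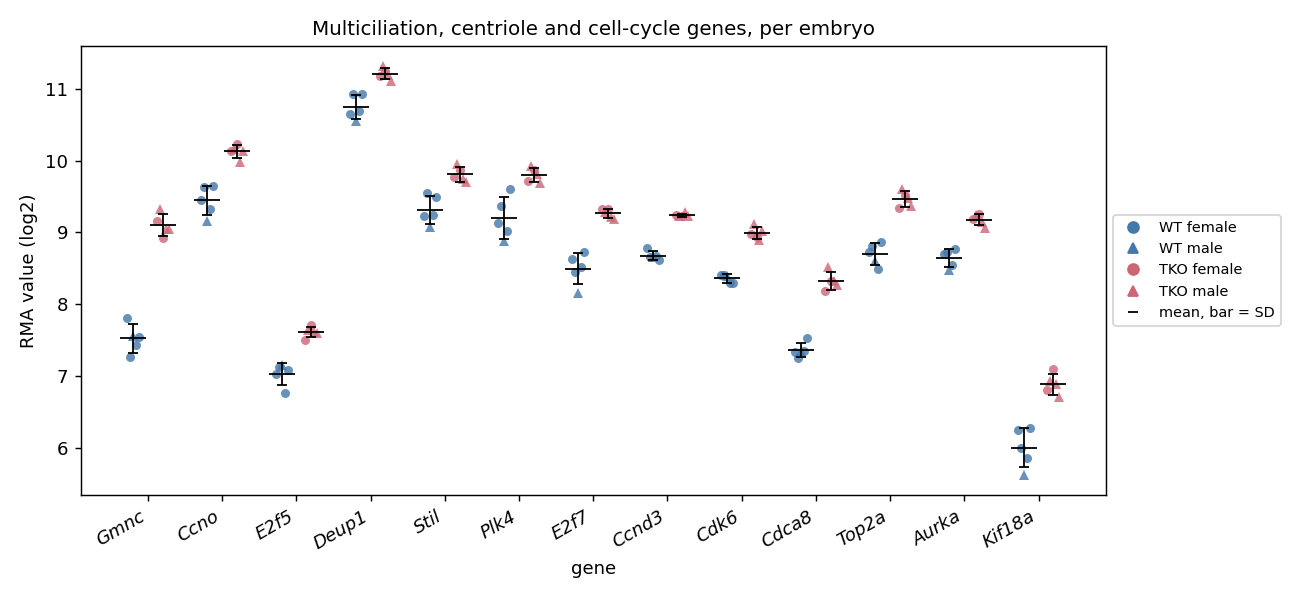
RMA values (log2) of 13 named genes of the multiciliation, centriole and cell-cycle lists, with 1 point per embryo (circles female, triangles male), a horizontal line at the mean and bars of 1 SD, n = 5 per genotype. For every one of these genes the 5 TKO values lie above the 5 WT values, as for Gmnc with 9.10 in TKO and 7.52 in WT.

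The G2/M and mitosis list held the most increases of the 29 lists. Of 81 tested members of the G2/M and mitosis list, 39 rose, none fell and 42 did not pass; adjusted over the list alone, 62 rose and 1 fell. Cdca8, a subunit of the chromosomal passenger complex, rose from 7.36 ± 0.10 to 8.32 ± 0.12 (1.92-fold, limma adjusted p = 0.00023), the kinesin gene Kif18a rose 1.98-fold, Top2a, the DNA topoisomerase of dividing cells, rose from 8.70 ± 0.16 to 9.46 ± 0.11 (1.71-fold), and the mitotic kinase gene Aurka rose as well (log2 change 0.58). The median change of the list was 0.37 (camera adjusted p = 4.85e-28, and adjusted p = 0.267 with an estimated correlation). Its score was higher in all 5 TKO than in any WT embryo, by 0.34 (exact permutation p = 0.00794, adjusted 0.0921). With the non-epithelial score as a covariate the median was 0.29.

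Of 66 tested genes of G1/S and DNA replication, 7 rose, 1 fell and 58 did not pass, the same counts as adjusted over the list alone. E2f7, a repressor among the E2F factors, rose from 8.49 ± 0.22 to 9.27 ± 0.06 (1.82-fold, limma adjusted p = 0.000322), the D-type cyclin gene Ccnd3 rose from 8.68 ± 0.06 to 9.24 ± 0.02 (1.48-fold), Cdk6, its kinase partner, rose from 8.36 ± 0.06 to 8.99 ± 0.08 (1.53-fold), and Dbf4, the activator of the replication kinase, rose 1.46-fold. Cdk4, named because it was the 1 member that fell, had a log2 change of -0.33. The median was 0.12 (camera adjusted p = 0.000528, and adjusted p = 0.692 with an estimated correlation), and the score per embryo was higher by 0.11 (exact permutation p = 0.0873). Of 27 inhibitors of the cell cycle and genes of cell-cycle exit, 3 rose: Cdkn3 (2.06-fold, 6.38 ± 0.20 to 7.43 ± 0.19), Cdkn2c (1.45-fold) and Lin54 (1.36-fold). The call of Lin54 was lost in 8 of 24 settings, its log2 change went as low as 0.22, and its arrays overlapped between genotypes. The other 24 did not pass, Cdkn1a among them (log2 change 0.30, limma adjusted p = 0.0501), and 6 rose when adjusted over the list alone. This list's median was 0.12 (camera adjusted p = 0.00372, and adjusted p = 0.366 with an estimated correlation; exact permutation p of the score 0.0159), and its camera call was lost with the non-epithelial score as a covariate (adjusted p = 0.0737). Cdkn3 is a phosphatase whose transcript is known to rise with mitosis. Of 15 replication-dependent histone genes, H4c1 (log2 change 0.75) and H4c8 rose, and 13 did not pass, with H4c14 at -0.18 and H2ac15 at 0.14; adjusted over the list alone the same 2 passed, and camera gave an adjusted p of 0.625.

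**Figure D4:**
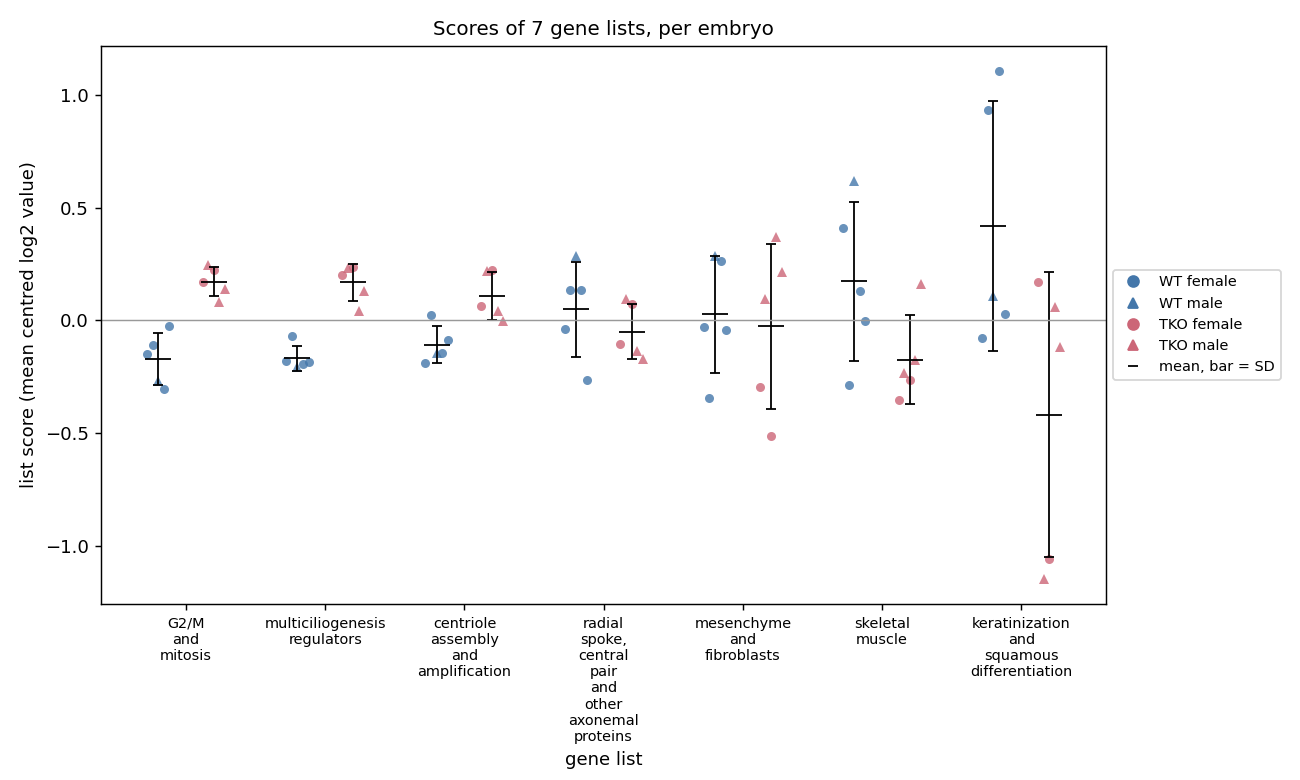
Scores of 7 gene lists (mean over members of log2 values centred on each gene's mean), with 1 point per embryo (circles female, triangles male), a horizontal line at the mean and bars of 1 SD, n = 5 per genotype. The G2/M and multiciliogenesis scores of the genotypes do not overlap, while those of the axonemal, mesenchyme, skeletal muscle and keratinization lists do (exact permutation p = 0.0952 for keratinization).

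Among genes reported elsewhere as targets of miR-34 and miR-449, increases outnumbered decreases, as they did over all changed genes, of which 79.7% were higher. Of 55 tested, 8 rose, 1 fell and 46 did not pass; adjusted over the list alone, 15 rose and 3 fell. Ccnd3, Cdk6 and E2f5 are members of this list too, and Jag1, a ligand of Notch receptors, rose from 7.75 ± 0.16 to 8.44 ± 0.19 (1.67-fold, limma adjusted p = 0.00372). The median was 0.11 (camera adjusted p = 0.0381, and adjusted p = 0.535 with an estimated correlation, exact permutation p of the score 0.0159). Without sex in the model the median was 0.056 (camera adjusted p = 0.0378). The camera call was lost in 12 of 26 settings, among them without WT 3 (median 0.079, adjusted p = 0.0625), WT 2, TKO 1 or TKO 2, among females only (adjusted p = 0.0771) and with the non-epithelial score as a covariate (median 0.088, adjusted p = 0.121). The fits without WT 3 and with females only gave the same median. Jag1 was the only 1 of 34 Notch pathway genes to pass, also when adjusted over the list alone; Hes6 (0.32), Notch2 (0.23) and Numbl (-0.29) did not. The list's median was below 0 (-0.0067) while its mean (0.021) and its camera direction were above (adjusted p = 0.839). Of 28 p53 target genes, 1 rose, Ckap2, a spindle protein (1.68-fold), and Mdm2 (0.36), Ccng1 (0.38) and Cdkn1a did not pass. Adjusted over the list alone, 5 rose and 2 fell (camera adjusted p = 0.424).

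Few markers of other epithelial cells passed, while the keratinization list had the lowest median of the 29 lists. Of 24 basal cell genes 1 fell, Ngfr (1.31-fold, a call lost in 16 of 23 settings), and Sfn (-0.43), Itga6 (0.22) and Lamb3 (-0.16) did not pass. The median was -0.13 (camera adjusted p = 0.0344, and adjusted p = 0.703 with an estimated correlation; exact permutation p of the score 0.262), and the call was lost with the non-epithelial score as a covariate (adjusted p = 0.0615). None of 32 secretory and glandular genes passed: Muc16 (0.52), Scgb3a1 (0.85), Muc1 (0.49) and Bpifb1 (0.84) had the smallest p. The secretory median was 0.081 (camera adjusted p = 0.424), and with the non-epithelial score as a covariate it was 0.19 and camera with the preset correlation called the list higher (adjusted p = 0.0109). Without the covariate, an estimated correlation gave an adjusted p of 0.85, and the score did not separate the genotypes (exact permutation p = 0.127). Among 38 genes of general epithelium 1 rose, Ovol2 (1.34-fold), while Ap1m2 (0.36), Tjp3 (-0.24) and Grhl2 (-0.21) did not pass, and the median was -0.051 (camera adjusted p = 0.623). None of 19 genes of ionocytes, tuft and neuroendocrine cells passed (Ascl3 0.45, Resp18 -0.37, Il25 -0.16, Foxi1 0.19). The list's median (0.026) and mean (-0.0084) differed in sign, and camera gave an adjusted p of 0.793 with a direction below 0. Of 32 olfactory genes, Nqo1 (1.43-fold) and S100a5 (2.24-fold, from a dim WT mean of 4.33) rose and Ermn (1.03) and Stoml3 (-0.44) did not pass. The median was 0.037 with sex in the model and -0.28 without it (camera adjusted p = 0.793 and 0.046). With sex in the model, an estimated correlation gave an adjusted p of 0.937. None of 29 genes of keratinization and squamous differentiation passed, with log2 changes of -0.77 for Tgm1, -1.58 for Dsg1a, -0.44 for Klk7 and -1.67 for Dsc1. The median was -0.77 (camera adjusted p = 2.7e-05, adjusted p = 0.535 with an estimated correlation, and exact permutation p of the score 0.0952), and it was -0.33 with the non-epithelial score as a covariate (camera adjusted p = 0.02). A few arrays carried this difference: the keratinization score was 0.93 in WT 2, 1.10 in WT 4, -1.14 in TKO 2 and -1.06 in TKO 3. On the other arrays of both genotypes it lay between -0.12 and 0.17.

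With sex in the model, markers of tissues under the epithelium were lower on balance, with few single genes past the test. Of 29 skeletal muscle genes 3 fell, the troponin genes Tnni2 (1.82-fold) and Tnnt3 (2.01-fold) and the titin gene Ttn (1.47-fold, a call lost in 14 of 23 settings), and Tnnc2 (-0.65) did not pass. Adjusted over the list alone 9 fell, and the median was -0.33 (camera adjusted p = 3.83e-08, and adjusted p = 0.366 with an estimated correlation; exact permutation p of the score 0.111). Of 32 mesenchyme and fibroblast genes 1 fell, the collagen gene Col3a1 (1.39-fold, a call lost in 6 of 24 settings), and Vim (-0.36), Six2 (0.20) and Postn (-0.90) did not pass. Adjusted over the list alone 2 fell, and the median was -0.19 (camera adjusted p = 5.75e-05, and adjusted p = 0.535 with an estimated correlation; exact permutation p of the score 0.794). Without sex in the model the mesenchyme call was lost (median -0.080, camera adjusted p = 0.299). Of 25 endothelial and pericyte genes 2 fell, Ramp2 (1.33-fold, a call lost in 12 of 24 settings) and Tie1 (1.31-fold, lost in 14 of 23), and Icam2 (-0.62) and Cdh5 (-0.68) did not pass. Adjusted over the list alone 4 fell, and the median was -0.17 (camera adjusted p = 0.00021, and adjusted p = 0.366 with an estimated correlation; exact permutation p of the score 0.23), a call also lost without sex (adjusted p = 0.0644). Of 13 glial genes 1 fell, Ngfr again, and S100b (-0.68), Erbb3 (-0.23) and Mal (-0.29) did not pass (median -0.11, camera adjusted p = 0.01, and adjusted p = 0.267 with an estimated correlation; exact permutation p of the score 0.0714).

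None of 25 leukocyte genes passed (Spi1 -0.29, Itgam -0.37, Adgre1 -0.25, Cma1 -0.45). The median was -0.12 (camera adjusted p = 0.0381, and adjusted p = 0.801 with an estimated correlation; exact permutation p of the score 0.881), and it was 0.0076 without sex in the model. None of 24 cartilage and bone genes passed (Col27a1 -0.23, Hapln1 0.38, Chad 0.55, Col11a2 -0.34). The median was -0.16 with sex in the model, and the score without it differed by 0.037 (camera adjusted p = 0.128, exact permutation p of the score 0.905). Without WT 3 the cartilage median was -0.27 and camera with the preset correlation called it lower (adjusted p = 0.0185). Females only gave the same median, which is no separate check (camera adjusted p = 0.0236). An estimated correlation with all arrays gave an adjusted p of 0.802. Of 14 erythroid genes 1 rose, Trim10 (1.27-fold, a call lost in 14 of 24 settings), and Xk (0.26), Sptb (-0.24) and Hba-x (-0.36) did not pass (camera adjusted p = 0.587). With the non-epithelial score as a covariate, camera no longer called the mesenchyme, endothelium, leukocyte and glia lists (adjusted p = 0.925, 0.151, 0.119 and 0.265). With the preset correlation it still called the skeletal muscle list, which is part of that score, at a median of -0.16 against -0.33 before (adjusted p = 0.00426), and did so without sex in the model, at -0.22 (adjusted p = 0.000209).

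Few genes passed in the lists that speak to RNA quality and cell stress. Of 30 immediate early and heat-shock genes 1 fell, Fos (1.44-fold, a call lost in 14 of 24 settings), and Hspb1 (-0.28), Ccn1 (-0.35) and Egr3 (-0.27) did not pass. The median was -0.070 (camera adjusted p = 0.0446, and adjusted p = 0.703 with an estimated correlation; exact permutation p of the score 0.31), and the list's call was lost in 11 of 26 settings. Of 57 cytosolic ribosomal protein genes 1 rose, Rpl3 (2.29-fold), although a further probe set of Rpl3 was at -0.11. Rpl34 (0.29), Rpl6 (0.28) and Rps13 (-1.91, with SDs of 0.29 in WT and 2.35 in TKO) did not pass, and the median was 0.011 (camera adjusted p = 0.759). Without WT 3 the ribosomal median was -0.047 and camera with the preset correlation called the list lower (adjusted p = 0.0443). Females only gave the same median (camera adjusted p = 0.04998). An estimated correlation with all arrays gave an adjusted p of 0.931. Of 66 oxidative phosphorylation genes 1 rose, Ndufa1 (1.24-fold), and Cox7a2 (0.19), Ndufa8 (0.18) and Cox4i1 (0.13) did not pass (camera adjusted p = 0.315). This list gained a camera call in 1 of 26 settings (adjusted p = 0.0271). Of 26 interferon response genes 1 rose, Oasl1 (1.29-fold, a call lost in 13 of 24 settings), and Cmpk2 (0.44), Herc6 (-0.31) and Rtp4 (-0.27) did not pass (camera adjusted p = 0.355).

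Adjusted over the list alone, 2 general epithelium genes rose and 2 fell, 2 glial genes fell, 2 erythroid genes rose, and no intraflagellar transport, immediate early or interferon gene passed. The counts of the dynein, basal, secretory, ionocyte, olfactory, keratinization, leukocyte, cartilage, ribosomal and oxidative phosphorylation lists were as over all genes. Over the 29 lists, camera with the preset correlation called 6 higher and 10 lower, and none with a correlation estimated from the arrays (3 at an unadjusted p below 0.05). Random splits of the arrays gave up to 18 lists called with the preset correlation, as described below. The exact permutation test on the scores per embryo called none after adjustment and 6 before it. Its smallest p, 0.00794, passes after adjustment over 29 lists only if several lists lie at or near that floor. Only the G2/M and multiciliogenesis scores separated the genotypes fully, so the adjusted result does not count against those lists. The multiciliogenesis score includes Cdc20b, Ccno and Mcidas, which lie beside the Mir449 cluster. It was not computed without them, so its separation may rest partly on that locus. The fry test, which asks whether a list's genes move one way on balance and does not compare them with other genes, passed 7 lists after adjustment, and its mixed form, for changes in either direction, passed 18.

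Changed genes were more frequent around the targeted loci than elsewhere. Within 5 Mb of the Mir34a, Mir34b/c and Mir449 loci, 24 of 219 tested genes had changed, against 888 of 16288 genes elsewhere (5.45%) (two-sided Fisher's exact test, p = 0.00143). Within 1 Mb of the Mir449 cluster, 5 of 15 genes had changed, and all rose: Cdc20b, Gzma, Ccno, Gpx8 (0.78) and Mcidas (0.55), a transcriptional activator of multiciliation. Gpx8 and Mcidas fall outside the rule for named genes and were named after their values were seen. The 5 were the tested genes nearest to the cluster, and none of the others within 1 Mb passed. Within 1 Mb of Mir34b/c, 9 of 28 genes had changed (32.1%, Fisher's exact p = 1.23e-05), 6 of them higher, and Btg4 was among those that fell. Within 5 Mb of Mir34a, 5 of 101 genes had changed (4.95%, Fisher's exact p = 1).

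Sex was a covariate in the limma, camera and fry results above unless stated otherwise, and not in the exact permutation tests, the scores per embryo or the counts of arrays that do not overlap. The difference between the sexes in the response to genotype could be tested only against the single WT male. The interaction of genotype and sex passed for 1 gene in limma, Rps13 (-3.65, adjusted p = 0.0124), and 705 genes had an unadjusted p below 0.05; without the variance trend the counts were 1 and 730. Rps13 was lowest in the 3 male TKO embryos, and sex cannot be told apart there from another difference between those embryos. The main effect of sex passed for 6 genes.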

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

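The test of the genes around the Mir449 cluster against the rest of their chromosome, and the use of the non-epithelial score as a covariate, were chosen after the results were seen. The number of genes that differed between genotypes is more than random splits of the arrays give. Of 100 splits of the 10 arrays into 5 and 5, drawn from 126, 1 gave as many genes, the real one with 916, and the highest of the other splits gave 2. The number of lists that camera called with the preset correlation is not. At least 16 lists, as in the real split, came from 10 of the 100 splits, the real one included. The other splits gave from 2 to 18, so chance cannot be excluded for that count. Camera with the preset correlation thus called lists when the genotypes were mixed, so a single such call is weak evidence by itself.

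The first pattern is the higher level of cell-cycle lists in TKO, above all of G2/M genes. Non-epithelial tissue, sex and a larger share of epithelium could each be behind it. For the G2/M list alone, the values below speak against each as its only source. With the non-epithelial score as a covariate the G2/M median kept 79.2% of its value, and among females alone it kept 86.7%. The same covariate cost the list of cell-cycle inhibitors its camera call (adjusted p = 0.0737). It took the multiciliogenesis and centriole medians from 0.28 and 0.25 to 0.16 and 0.12, so the G2/M values do not speak for those lists. The general epithelium list's median was -14.0% of the G2/M median (difference 0.42, 95% bootstrap interval over genes 0.30 to 0.47). That interval resamples genes and not embryos, so it holds no variation between captures. The general epithelium score per embryo differed by -0.042 (exact permutation p = 0.452), so what stands against a larger share of epithelium is that this list was not higher. More cycling cells, or cells held before multiciliation, may account for the pattern. The G2/M score differed between genotypes (exact permutation p = 0.00794). More cycling cells would be looked for in the G1/S list too, whose score was higher by 0.11 and did not pass (exact permutation p = 0.0873). Camera called the G1/S list higher with the preset correlation (adjusted p = 0.000528) and not with an estimated one (adjusted p = 0.692). The G1/S values thus do not decide on more cycling cells, and cells held before multiciliation were not tested separately. The 2 explanations cannot be told apart from a rise of mitotic genes inside multiciliated precursors, since a capture averages over cells.

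The second pattern is the lower median of all 6 non-epithelial lists in TKO with sex in the model. Less underlying tissue in the TKO captures could produce it. The 6 scores moved together over the arrays within genotypes, with a mean pairwise correlation of 0.648. A varying share of such tissue would give that, but it does not test a difference between genotypes. Without sex, the medians of mesenchyme, endothelium and cartilage were -0.080, -0.085 and -0.036, against -0.19, -0.17 and -0.16 with it. Glia went from -0.11 with sex to -0.16 without it. The non-epithelial score was -0.23 and -0.32 in the female and -0.033, 0.15 and 0.15 in the male TKO embryos. In WT it was 0.26 in the male and -0.28 to 0.19 in the females. The score itself did not separate the genotypes (difference -0.11, exact permutation p = 0.405), and without sex in the model the leukocyte median was 0.0076, while skeletal muscle, 1 of the 6 lists in the score, was called lower by camera with the preset correlation without sex (-0.22) and with the score as a covariate (-0.16 against -0.33), and not with an estimated correlation (adjusted p = 0.366). No biological explanation was tested for it.

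The third pattern is the excess of changed genes around the targeted loci. The excess within 5 Mb of the 3 loci (Fisher's exact p = 0.00143) is the pattern itself and does not test its source, and DNA of the donor strain left beside each locus, which may account for it, would be looked for at each: Mir34a had 4.95% changed against 5.53% elsewhere. Around Mir34a or Mir34b/c pooled, the excess passed within 5 Mb (Fisher's exact p = 0.0204) and 20 Mb (p = 0.0196) and missed the threshold within 10 Mb (7.13% against 5.48%, p = 0.153), where Mir34b/c alone passed (10.1%, p = 0.00831) and Mir34a had 4.02%, so donor DNA at Mir449 stays open without being shown. An effect of the deletion on its neighbours in cis could likewise account for the 5 higher genes around Mir449. Their excess over the rest of the chromosome (Fisher's exact p = 0.00102) is again the pattern itself and does not test this source. An effect in cis stays open at Mir34b/c too, where the nearest tested genes, Btg4 (-0.88) and Hoatz (0.52), both changed, in opposite directions. The microRNAs' loss acting on the multiciliation programme stays open as well, since Cdc20b, Ccno and Mcidas belong to it. Gzma and Gpx8 are not on the multiciliogenesis list. The 5 higher genes around Mir449 were the tested genes nearest to it, as either local source would give, and these explanations were not separated.

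Some values stood far from the others of their genotype, as measured by the gap to the nearest array over the range of the 5 arrays, in 20 of 342 groups tested; chance flags about 1 in 20. In WT 3, the only WT male, the ratio was 0.946 for Xist, 0.734 for Eif2s3y, 0.911 for Kdm5d and 0.864 for Uty, which is its sex, and 0.744 for Rpl34. In WT 2 it was 0.806 for the multiciliogenesis score and 0.726 for Jag1, in WT 1 it was 0.730 for Cdkn3, and in WT 4 it was 0.877 for Il25 and 0.714 for Egr3. In TKO 4 it was 0.835 for the G1/S score and 0.766 for Ccnd3. In TKO 5 it was 0.816 for the basal cell score, 0.716 for Ngfr, 0.754 for Tnnc2 and 0.747 for Herc6. In TKO 3 it was 0.717 for the secretory score and 0.716 for Hes6, and in TKO 1 it was 0.719 for H4c14 and 0.772 for Mir449b.

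The difference between the sexes in the effect of genotype rests on the single WT male. Rps13 differed by -3.65 (male minus female effect, limma adjusted p = 0.0124). On single arrays Rps13 was 9.03 and 9.84 in the female TKO embryos, 5.58, 4.99 and 5.00 in the male ones, and 9.43 in WT 3. These values cannot tell sex from another difference between the TKO embryos. Camera with the preset correlation found a difference for 14 lists. Their median differences were -0.30 for axonemal dyneins, -0.32 for radial spoke and other axonemal genes, -0.29 for intraflagellar transport, 0.092 for G1/S, 0.26 for replication-dependent histones, 0.17 for basal cells and -0.14 for secretory cells. They were 0.21 for cartilage and bone, 0.17 for mesenchyme, 0.18 for leukocytes, -0.32 for skeletal muscle, 0.12 for immediate early genes, 0.19 for cytosolic ribosomal proteins and 0.30 for keratinization. With an estimated correlation none passed, the smallest adjusted p being 0.646.

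Among the 16010 probe sets with no listed gene, which the comparison of genes does not use, 105 passed an adjusted p of 0.05 in limma, 68 higher and 37 lower in TKO.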

How the results depend on the processing

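The settings with the non-epithelial score and without genes near the loci were chosen after the data were seen; the cause of a change was not tested unless it is given. Of 131 named genes 128 kept their sign in each of up to 24 settings, and 12 passed in all of them: Mir449c, Mir449a, Cdc20b, Gmnc, Gzma, Ccnd3, Cdk6, E2f7, Cdca8, Doc2b, Fam167a and Tmem108. Of 29 lists 14 kept the sign of their median. All 916 genes kept their direction in each setting that tested them, except that the fit to all probe sets was not matched by gene. The 916 genes were chosen on these same arrays, so this was largely built in. The seed-site test was not run for lack of transcript sequences, nor were its alternatives. Signal over background limits Mir34a and Mir34c, whose probe sets were dim in both genotypes.

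The replicate numbers do not pair the arrays: the same-numbered deviations correlated at -0.157, 0.104, 0.125, 0.368 and 0.0653, and not every array correlated best with its own number. With the replicate number as a block, 1053 genes passed, 282 of them lower, and the ionocyte median was -0.00014.

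Counts of genes moved as follows. Females only, with 6 arrays, gave 56 genes (52 higher, 4 lower); the 916 genes' median change was then 0.46 with a median standard error of 0.12. The non-epithelial score gave 111 (96 higher, 15 lower), and all probe sets, with more features tested, gave 555 (463 higher, 92 lower). Leaving out 1 array gave from 210 without WT 3 to 1284 without WT 5, with 191 to 886 higher and 19 to 398 lower. Without WT 3 the males are all TKO, so that by construction the genotype effect comes from the females.

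Counts of lists moved with the estimated correlation, to 0 higher, 0 lower and 0 in all, while the medians stayed at -0.090 for dyneins, 0.25 for centrioles, 0.12 for G1/S, 0.37 for G2/M, 0.28 for multiciliogenesis and -0.12 for radial spokes. Without sex 6 lists were lower; with the non-epithelial score 5 were lower and 10 changed in all; with 1 array left out 6 (without TKO 1) to 10 were lower. The dynein list lost its call without sex (-0.073), with array quality (-0.083), and without any 1 of WT 2, WT 4, TKO 1, TKO 4 and TKO 5, and its median changed sign without WT 3, so that leaving out 6 of the 10 arrays in turn ended it. Of 26 settings, the call was lost or the sign changed in 12 for the reported targets, 12 for leukocytes, 11 for immediate early genes and 8 for basal cells. Leaving out 1 array did so for the targets with WT 2, WT 3, TKO 1 or TKO 2, for leukocytes with WT 1, WT 4, WT 5, TKO 1, TKO 2 or TKO 3, for immediate early genes with WT 1, WT 2, WT 4, TKO 1, TKO 2 or TKO 3, and for basal cells with WT 1, WT 5, TKO 1, TKO 3 or TKO 4. The intraflagellar transport list gained a call with the filter at the median, a second quantile normalization, the non-epithelial score, or without WT 5, TKO 2 or TKO 3, and its median was above 0 among females and without WT 3 or TKO 4. The dynein median ran from -0.17 to 0.0098 with 1 array left out, and that of radial spokes from -0.21 to 0.0066; among females they were 0.0098 and 0.0066.

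Other medians changed sign, mostly near 0. Females only gave -0.047 for ribosomal proteins, 0.020 for interferon, 0.041 for intraflagellar transport, -0.019 for ionocytes and -0.10 for histones, with H2ac15 at -0.23. Among these lists, camera with the preset correlation called the ribosomal one lower (adjusted p = 0.04998). The non-epithelial score gave 0.078 for cartilage, 0.016 for interferon, 0.073 for leukocytes, 0.020 for mesenchyme and -0.0090 for olfactory genes, with Ccn1 at 0.10 and Itgam at 0.035; cartilage, leukocytes and mesenchyme are part of that score. No sex term gave -0.0068 for ribosomal proteins, -0.032 for ionocytes, 0.0076 for leukocytes and -0.28 for olfactory genes. Median centring gave -0.0017 for ribosomal proteins and -0.0045 for p53 targets, and a second quantile normalization gave -0.0085 and -0.0051. The filter at the median gave 0.051 for erythroid, 0.017 for Notch and -0.022 for p53 genes, and no filter gave -0.0095 for p53 and -0.022 for secretory genes. Array weights gave -0.0027 for ionocytes and -0.014 for histones. Array quality gave -0.00011 for olfactory genes and -0.0020 for p53 targets. The mean of probe sets gave 0.0067 and the removal of genes near the loci 0.00032 for Notch, and leaving out shared members gave -0.0095 for p53 targets.

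With 1 array left out, the ranges were -0.23 to 0.30 for H2ac15, -0.047 to 0.053 for ribosomal proteins, -0.084 to 0.020 for interferon, -0.067 to 0.041 for intraflagellar transport, -0.019 to 0.051 for ionocytes, -0.031 to 0.030 for Notch, -0.10 to 0.17 for olfactory genes, -0.013 to 0.037 for p53 targets and -0.10 to 0.079 for histones.

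The excess of changed genes near the 3 loci together held at 10 and 20 Mb (Fisher's exact p = 0.00788 and 0.00161). No list passed the exact test on scores after adjustment under any of 3 alternatives, and 6 did before it in the setting reported.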

Other observations

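The genes below were chosen after their values were seen. Captures of both genotypes differed from embryo to embryo in genes of bone and its matrix. Mmp13, a collagenase of bone and cartilage, ran from 3.52 to 9.01 in WT and from 3.80 to 9.89 in TKO. Ibsp, bone sialoprotein, ran from 4.83 to 10.20 in WT and from 5.34 to 10.11 in TKO, and Ctsk, the osteoclast protease, from 4.92 to 9.05 and from 5.10 to 9.51. None of these differed between genotypes (limma adjusted p = 0.417, 0.697 and 0.341). In TKO, the values in the 2 female embryos, 4.78 and 3.80 for Mmp13, lay below those in the 3 male embryos, 9.06, 9.89 and 9.54, so that in this genotype labelled sex and these genes moved together; among WT, Mmp13 was 8.97 in the male and 3.52 to 9.01 in the females.

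Cornified-layer genes varied within both genotypes as well, with smaller SDs than Mmp13. Krt10, a keratin of cornifying epidermis, ran from 8.98 to 12.35 in WT and from 7.71 to 11.38 in TKO, and Lor, the cornified envelope protein loricrin, from 7.15 to 10.49 and from 5.91 to 9.66 (limma adjusted p = 0.271 and 0.45). The score of the olfactory list, with an SD of 0.65 in WT and 0.54 in TKO, spread more than the difference between genotypes (-0.23, exact permutation p = 0.563).

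Trim34a, among the largest decreases, was low in the same TKO embryos as Rps13. It was 5.16, 5.23 and 4.54 in the 3 male TKO embryos, 6.68 and 6.85 in the 2 female ones, and 7.16 to 7.48 in WT. Both genes lie on the same chromosome in the gene table. The decrease of Trim34a thus differed in size between TKO embryos, with an SD of 1.02 against 0.15 in WT. For both genes, sex cannot be told apart from another difference between those embryos.

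Around Mir34a, where changed genes were no more frequent than elsewhere, the 5 that changed were Agtrap (0.89), Hes2 (0.57), Icmt (0.53), Espn (0.37) and Uts2 (-0.31). Around Mir34b/c, the genes within 1 Mb that changed besides Btg4 included Hoatz (0.52), Il18 (0.92), Nkapd1 (0.55) and Pts (-0.49). Hoatz is a gene of motile cilia, and Il18 encodes a cytokine. Btg4 and Hoatz were the tested genes nearest to Mir34b/c.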
